A study of Mus musculus with 24 samples.

How the data were processed

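RNA of sorted CD4 T cells was measured on 24 Affymetrix Mouse Gene 1.0 ST arrays, which carry oligonucleotide probes along the exons of mouse genes. The cells came from male C57BL/6 mice with a green fluorescent protein (GFP) reporter inserted behind Foxp3, the transcription factor that defines regulatory T cells. Skeletal muscle had been injured with cardiotoxin, a snake venom component that destroys muscle fibres and starts their regeneration. Per the labels, cells positive for the T cell receptor beta chain and CD4 were sorted as GFP positive regulatory T cells (Treg) or GFP negative conventional T cells (Tconv), with CD8a, CD11b, CD11c, CD49b, CD19 and Ter119 among the exclusion markers. The 8 groups combine cell type, tissue (muscle or spleen) and day after injury (4 or 14), with 3 arrays each. Each array pooled several mice, and p-values use 1 spread per gene over all groups.

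The authors deposited 1 intensity per probe set and array on a linear scale, from 4.831 to 29623. The submitters' processing notes name Affymetrix Power Tools and RMA, which subtracts background, normalizes between arrays and summarises the probes of a probe set. Versions, settings and the genome build behind the probe annotation are not given in the sources used here. RMA lessens differences near the background, and detection calls were not used here. Folds against a group under the filter level given below are ratios of deposited values that may be compressed, and their order is not measured. The median intensity per array ran from 80.82 to 95.15, so the deposited columns were not identical in distribution. The log2 of each value was taken with no pseudocount. The number of arrays limits the precision of each value.

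Of 24922 probe sets, 21425 carried a single gene symbol, 1399 carried several and 2098 were not listed with a gene. The last 2 kinds were left out of the comparisons. Of the 21425, 21347 were matched by Entrez identifier to the mouse gene table of the reference (0 symbols changed). Positions of probe sets on the genome were not used here. A probe set was kept where it exceeded the median of all values, 88.3 intensity units or 6.46 on the log2 scale, in at least 3 arrays. This left 12141 probe sets, and the brightest per gene was kept, which gave 11113 genes out of 19752.

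A linear model with a mean for each of the 8 groups was fitted to each gene over all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, residual degrees of freedom 16, prior 5.72). All tests were two-sided. The contrasts were 12 comparisons of groups and 4 interactions, each of which tests whether a difference differs between cell types, tissues or days. P-values were adjusted by Benjamini-Hochberg over all genes within a contrast, and genes were called at an adjusted p under 0.05. For a single gene, 3 arrays against 3 allow no exact permutation p under 0.1. Fold changes are given on the log2 scale with the standard error (SE) from limma, and group levels as mean log2 intensity with the SD of 3 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

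The groups, comparisons, tests, filter, gene lists, naming rule and most alternatives were chosen before the data were examined. There were 29 gene lists. The 19 lists of T cell programmes were the Treg signature, conventional T cell-high genes, naive and lymphoid-homing genes, effector and memory T cell genes, activated and tissue Treg genes, inhibitory receptors, TNF receptor family and costimulatory receptors, chemokine receptors and trafficking, cytokines and chemokines, growth and repair factors, Th1 and cytotoxic genes, Th2 genes, Th17 genes, cell cycle genes, interferon-stimulated genes, immediate-early and stress genes, hypoxia and glycolysis genes, cholesterol synthesis genes, and oxidative phosphorylation genes. The 10 lists for other cells held markers of macrophages and monocytes, dendritic cells and antigen presentation, neutrophils, B cells, NK and CD8 T cells, erythroid cells and platelets, muscle fibres, satellite cells and myoblasts, fibroblasts and matrix, and endothelium. Lists may share members. The lists were written from general knowledge, part of which may go back to this study, so their directions are not independent evidence. The 23 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, which compares a list with all other genes. Benjamini-Hochberg was applied over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were alternatives. Counts of members called over all genes stand beside counts adjusted over the list alone. For no called list did the median, the mean and the direction of camera differ in sign, and among lists that were not called they differed in some.

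Genes were named by rule. Foxp3 came first in every group. The 5 main comparisons took the 8 largest rises and the 8 largest falls among called genes with no overlap between the 3 and 3 arrays, a separation that chance gives a gene with a share of 0.1. Other comparisons and interactions took 4 and 4. Antigen receptor segments, genes without a proper name, small RNAs and histone clusters were excluded. Up to 4 called members per list and 18 fixed genes were added, of which Areg, Il1rl1, Sell and Tcf7 were not listed alone on any probe set and were not analysed here.

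The alternatives chosen beforehand were no filter, a stricter filter (7.07, the 60th percentile), the mean of all probe sets per gene, repeated quantile normalization, centring of each array on its median, trend and robust eBayes, array weights, a fit to the arrays of the comparison only, the replicate number as a block, a pseudocount of 16 and leaving out each array in turn. Chosen after the data were seen were the replicate number within each day as a block, leaving out the 4 replicate 1 arrays of day 4 together, camera on the interactions, and camera with each array left out in turn.

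Labels give replicate numbers but not what same-numbered arrays share. Pairs were checked by correlating departures of same-numbered arrays from group means across genes. All 3 correlations exceeded 0.1 in 4 comparisons: muscle against spleen Treg at day 4 (0.656, 0.198 and 0.398), Treg against Tconv in muscle at day 4 (0.665, 0.344 and 0.443) and in spleen at day 4 (0.572, 0.496 and 0.489) and 14 (0.403, 0.126 and 0.407). Blocked values stand beside these. Departures sum to 0, so a shift of number 1 can raise all 3. The fit was tested on 1 simulated draw of independent genes with their own mean and residual SD, some changed in muscle Treg at day 14. Against spleen Treg it recovered 46% of 50 genes changed by 0.5, 90% at 1 and 100% at 2, with 14 false calls. In a second, camera called only the shifted list of 23. No correlated genes were drawn.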

Results

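Gene expression was compared between Treg and Tconv taken from cardiotoxin-injured muscle and from spleen at days 4 and 14 after injury. Treg restrain other T cells and are also found in tissues, and the design asks how those of injured muscle differ from those of a lymphoid organ, from the Tconv beside them and between an early and a later time of repair. Each of the 8 groups held 3 arrays. In each array 9365 to 10200 of the 11113 genes tested lay above the filter level. Across genes, which are not independent replicates, Pearson's r between arrays of a group was 0.949 to 0.991 outside the muscle Treg of day 4, where it was 0.892 to 0.969. The first 4 principal components held 38.3%, 17.9%, 13.4% and 10.5% of the variance.

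The replicate 1 arrays of day 4 stood apart in all 4 groups, and their departures from the group means correlated across genes at 0.342 to 0.772. Against the other arrays of their group, 33 oxidative phosphorylation genes lay higher by a median of 0.51 on the log2 scale and 59 ribosomal protein genes, a set chosen after the data were seen, by 0.36. In the same arrays 30 immediate-early genes lay at a median of -0.34, and cell cycle genes at -0.43 to 0.92 depending on the group. The replicate 1 arrays of day 14 lay higher in cell cycle genes by a median of 0.58. Values without these 4 arrays are given beside several gene groups below.

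Foxp3 (probe set 10598292), the gene behind the reporter, separated the sorted cells in every group. Its log2 intensity lay between 10.97 and 12.75 in the 12 Treg arrays and between 6.52 and 7.35 in the 12 Tconv arrays. Treg exceeded Tconv by 5.60 ± 0.27 (SE) in muscle at day 4, 5.35 ± 0.27 in muscle at day 14, 4.35 ± 0.27 in spleen at day 4 and 4.98 ± 0.27 in spleen at day 14. The adjusted p values, with 3 arrays per group, were 1.35e-12, 1.09e-12, 7.8e-11 and 8.02e-12.

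**Figure D1:**
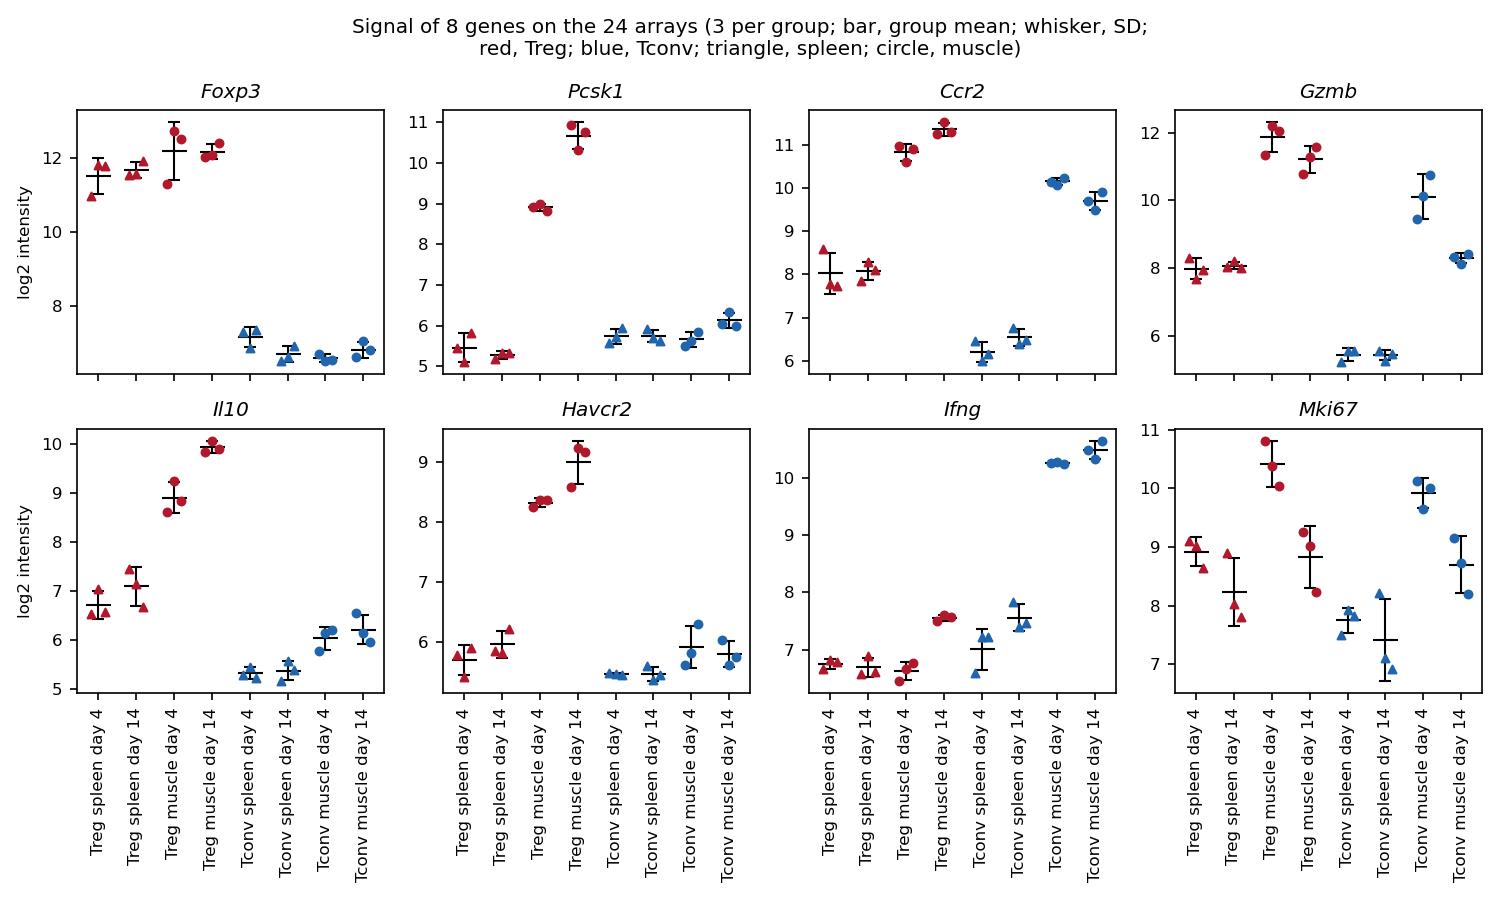
Log2 intensity of 8 genes on the 24 arrays, with Treg in red, Tconv in blue, spleen as triangles, muscle as circles, bars at the mean of 3 arrays and whiskers of 1 SD. Foxp3 separated Treg from Tconv, Pcsk1 averaged 10.67 in muscle Treg of day 14 against 5.28 in spleen Treg, and Ifng averaged 10.48 in muscle Tconv of day 14 against 7.56 in muscle Treg.

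Treg of injured muscle were first compared with Treg of the spleen at day 4. Gzmb, the granule protease granzyme B, averaged 11.86 ± 0.44 in muscle and 7.98 ± 0.31 in spleen (SD, n = 3 each), a 14.7-fold difference. Pcsk1 (probe set 10406229), a convertase that processes prohormones, was 10.9-fold higher, and Il10, an anti-inflammatory cytokine, was 4.54-fold higher. The chemokine receptors Ccr3 (3.00 ± 0.25) and Ccr2 (2.81 ± 0.19), the chemokine Cxcl10 (2.86 ± 0.19) and the inhibitory receptor Havcr2, also called Tim-3 (2.63 ± 0.18), rose as well. The survival factor Bcl2 (-2.56 ± 0.13), the orphan receptor Gpr83 (-3.40 ± 0.19), the adhesion receptor Cd96 (-2.35 ± 0.14) and Cxcr5, which guides cells to follicles (-2.27 ± 0.21), fell.

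By list, 27 of 29 activated and tissue Treg genes rose and 0 fell, with the same 27 when adjusted over the list alone (median 1.33, camera adjusted p = 7.84e-26), with Gzmb, Ccr2, Havcr2 and Fgl2 (2.24) among them. This list came from general knowledge of tissue Treg that may draw on this study, so its direction is not independent evidence in any comparison. Effector and memory genes followed, with 17 of 25 higher and 2 lower (18 and 2 adjusted over the list alone, adjusted p = 5.7e-11), among them Glrx (1.96), Prdm1 (1.92) and Bhlhe40 (1.90). Growth and repair factors rose in 8 of 14 members (9 adjusted over the list alone, adjusted p = 3.04e-07), with Il10, the protease Furin (1.17) and Pdgfb (1.17) among them, while Pdgfa did not pass (0.29 ± 0.16). Th17 genes rose in 7 of 9 (7 adjusted over the list alone, adjusted p = 3.04e-07), including the nuclear receptor Rora (1.63) and the receptor Il23r (1.50). Of 19 naive and lymphoid-homing genes 13 fell, including Bach2 (-2.12) and Ccr7 (-1.41), and 1 rose (13 and 1 adjusted over the list alone). That list passed at an adjusted p of 1.82e-10 and had an adjusted p = 0.0564 with an estimated correlation.

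Cell cycle genes rose in 48 of 60 members at a median of 1.01 (55 adjusted over the list alone, adjusted p = 2.15e-18, and adjusted p = 0.197 with an estimated correlation). Mki67, a marker of dividing cells, rose by 1.49 ± 0.33. Without the replicate 1 arrays of day 4, 20 members rose and 1 fell, and 30 or 31 rose without that of muscle Treg or spleen Treg alone. Interferon-stimulated genes rose in 16 of 30 (19 adjusted over the list alone, adjusted p = 5.96e-07, and 0.136 as the adjusted p with an estimated correlation), and in 9 without spleen Treg day 4 replicate 3. Without muscle Treg day 4 replicate 1, 15 rose and 3 fell. Of the Treg signature 11 members rose and 8 fell out of 26 (14 and 9 adjusted over the list alone), and the list did not pass (adjusted p = 0.294). The falls numbered 5 without muscle Treg day 4 replicate 1, and 4 or 5 without spleen Treg day 4 replicate 2 or 3. In it Klrg1 (1.98), Itgae (1.80), which encodes the CD103 integrin chain, and Tnfrsf9 (1.33) rose while Gpr83 fell. Foxp3 differed by 0.67 ± 0.27 (adjusted p = 0.0824) and passed with the replicate number as a block (adjusted p = 0.0381, range over 18 alternatives 0.000173 to 0.408). It differed by 1.11 without muscle Treg day 4 replicate 1 (adjusted p = 0.000611). Oxidative phosphorylation genes (adjusted p = 0.801) and cholesterol synthesis genes (adjusted p = 0.12) did not pass as lists. Without the replicate 1 arrays of day 4 the first had a median of -0.11 (adjusted p = 0.105) and the second passed (adjusted p = 0.0272). Oxidative phosphorylation genes passed at a median of -0.31 without muscle Treg day 4 replicate 1 alone (8 fell, adjusted p = 0.00404).

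In all, 2485 genes differed between muscle and spleen Treg at day 4, 1201 higher in muscle (257 by at least 2-fold) and 1284 lower (169). With the replicate number as a block the count was 2777, and 3190 with a block within each day. It was 870 with only the arrays of the comparison fitted (483 higher and 387 lower) and 4883 with array weights. Fibroblast markers did not pass (adjusted p = 0.0523) but did with the replicate block (adjusted p = 0.048), fry (0.037), without the replicate 1 arrays of day 4 (0.0178), and without muscle Treg day 4 replicate 1 (0.00704) or spleen Treg day 4 replicate 3 (0.0206).

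At day 14 in the same comparison Pcsk1 averaged 10.67 ± 0.32 in muscle Treg and 5.28 ± 0.09 in spleen Treg (SD, n = 3 each), the latter below the filter level. The chemokine receptor Ccr1 averaged 8.09 against 4.00, the phospholipid-binding protein Anxa1 8.24 against 4.84, and the nuclear lamina gene Lmna was 10-fold higher in muscle. Frmd5 (3.35 ± 0.14), Pcyt1a, an enzyme of phosphatidylcholine synthesis (3.29 ± 0.14), Ccr2 (3.28 ± 0.19) and Cxcl10 (3.15 ± 0.19) rose as well. Il10 rose by 2.84 ± 0.20, Klrg1 by 2.78 ± 0.25, Havcr2 by 3.05 ± 0.18 and Gzmb by 3.14 ± 0.26. Gpr83 (-3.86 ± 0.19), the transcriptional regulator Aff3 (-2.81 ± 0.15), Bcl2 (-2.69 ± 0.13), Igfbp4, which binds insulin-like growth factors (-2.72 ± 0.26), and the lymphoid homing receptor Ccr7 (-1.99 ± 0.17) fell.

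Activated and tissue Treg genes rose in 28 of 29 members, as many when adjusted over the list alone (median 1.41, adjusted p = 8.26e-37). Effector and memory genes rose in 21 of 25 and fell in 1, the same counts adjusted over the list alone (adjusted p = 1.46e-20), led by Anxa1, Ccr2, the transcriptional regulator Id2 (2.54) and Cxcr6 (2.36). Immediate-early and stress genes rose in 18 of 30 at a median of 1.12 (22 adjusted over the list alone, adjusted p = 3.53e-16), with Fosl2 (2.91), Nr4a3 (2.74), Gadd45b (2.54) and Fosb (2.43) in front. Cytokines and chemokines rose in 10 of 22 and fell in 1, unchanged over the list alone (adjusted p = 3.65e-05), including Ccl3 (2.83) and Cxcl2 (2.14). Th2 genes rose in 5 of 9 (adjusted p = 0.000292), including Ccr8 (2.03), and Th17 genes in 6 of 9 (adjusted p = 2.24e-07), with the same counts adjusted over the list alone. Naive and lymphoid-homing genes fell in 15 and rose in 1 of 19 (15 and 2 adjusted over the list alone, adjusted p = 3.43e-17). Conventional T cell-high genes fell in 7 and rose in 1 of 12, also over the list alone (adjusted p = 7.24e-10).

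Inhibitory receptors rose in 6 and fell in 2 of 10, also over the list alone (adjusted p = 0.000529), the rises including Havcr2, Klrg1, Cd200r1 (1.87) and Tigit (1.41). The list had an adjusted p = 0.109 with an estimated correlation. Chemokine receptors and trafficking genes rose in 12 and fell in 5 of 26 (13 and 5 adjusted over the list alone, adjusted p = 0.00159), the falls including Cxcr5 (-2.40). Their adjusted p was 0.12 with an estimated correlation. The Treg signature rose in 11 and fell in 4 of 26 (14 and 6 adjusted over the list alone, adjusted p = 0.00146, and adjusted p = 0.128 with an estimated correlation). Foxp3 itself (0.50 ± 0.27, adjusted p = 0.279) passed without the replicate 1 arrays of day 4 (adjusted p = 0.0192, range over 18 alternatives 0.00254 to 0.555). Only 2 of 60 cell cycle genes passed here (2 adjusted over the list alone), with a camera adjusted p = 0.00983 that became an adjusted p = 0.741 with an estimated correlation and 0.408 with fry. The list did not pass without muscle Treg day 14 replicate 1 (adjusted p = 0.545) or 2 (0.0563) or spleen Treg day 14 replicate 2 (0.132) or 3 (0.184), and 5 members rose without the replicate 1 arrays of day 4. At day 14, 1615 genes differed, 987 higher in muscle (309 by at least 2-fold) and 628 lower (131). The count was 2434 without the replicate 1 arrays of day 4, which enter through the shared estimate of the spread, and 3614 with array weights (1659 higher and 1955 lower).

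Within injured muscle at day 4, Treg were set against the Tconv sorted from the same tissue. Treg exceeded Tconv in Foxp3 (48.5-fold) and in Il2ra, the alpha chain of the interleukin 2 receptor, at 11.68 ± 0.35 against 7.57 ± 0.28 (SD, n = 3 each). Klrg1, a lectin-like receptor of differentiated lymphocytes, was 15.9-fold higher, Neb, which encodes the giant sarcomere protein nebulin, 12.5-fold, and Lrrc32, the receptor that holds latent TGF-beta on Treg, 11.3-fold. In Tconv the natural killer receptor Klrk1 was 16.1-fold higher, the phosphodiesterase Pde3b 14.5-fold and the cytokine Ifng 12.4-fold, with Treg minus Tconv at -4.01 ± 0.19, -3.86 ± 0.30 and -3.63 ± 0.15. Il12rb2 (-3.36 ± 0.20) and Fasl (-3.20 ± 0.17), a receptor for interleukin 12 and a death ligand, were also lower in Treg.

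The Treg signature was higher in 22 of 26 members and lower in 0 (22 and 1 adjusted over the list alone, median 1.54, adjusted p = 7.31e-27). Activated and tissue Treg genes were higher in 25 of 29 and lower in 2 (26 and 2 adjusted over the list alone, adjusted p = 4.72e-22), with Tnfrsf9 (3.47), Itgae (3.28) and the interleukin 1 decoy receptor Il1r2 (3.01) among them. Th1 and cytotoxic genes were lower in Treg in 16 of 19 and higher in 2, the same counts adjusted over the list alone (median -2.36, adjusted p = 8.49e-14), and Gzmb was an exception at 1.75 ± 0.26. Interferon-stimulated genes were lower in 23 of 30 and higher in 0 (25 and 1 adjusted over the list alone, adjusted p = 8.16e-12), including Ifit3 (-2.09), Oasl2 (-2.02) and Mx1 (-2.01). Growth and repair factors were higher in 5 of 14, also adjusted over the list alone (adjusted p = 2.67e-05; 8 after centring), led by Penk, which encodes the opioid precursor proenkephalin (2.93), and Il10 (2.86). Conventional T cell-high genes were lower in 11 of 12, likewise over the list alone (adjusted p = 5.84e-10, and adjusted p = 0.0591 with an estimated correlation), among them the CD40 ligand gene Cd40lg (-3.15) and Il2 (-2.54).

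Inhibitory receptors were higher in 6 and lower in 2 of 10 (adjusted p = 0.00224, and adjusted p = 0.174 with an estimated correlation), with 6 and 3 adjusted over the list alone. Havcr2 stood at 2.42 ± 0.18, Tigit at 1.67 ± 0.25 and Ctla4, a brake on costimulation, at 1.73 ± 0.27. Cell cycle genes had 6 of 60 members higher in Treg (5 adjusted over the list alone) at an adjusted p of 0.000132, which was an adjusted p = 0.6 with an estimated correlation, 0.318 with fry and 0.0539 without the replicate 1 arrays of day 4. The members higher numbered 14 after repeated quantile normalization, 16 after centring and 3 without those arrays, and the list did not pass without muscle Treg day 4 replicate 1 (adjusted p = 0.252). Mki67 did not pass (0.49 ± 0.33, adjusted p = 0.274) but did with a block within each day (adjusted p = 0.0385, range over 18 alternatives 0.0385 to 0.521). The 33 oxidative phosphorylation genes had a median of -0.16 (adjusted p = 0.574), which was 0.05 after repeated quantile normalization and -0.38 without the replicate 1 arrays of day 4 (adjusted p = 0.00506). The median was -0.46 without muscle Treg day 4 replicate 1 alone (13 lower, adjusted p = 0.00297).

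In all, 2973 genes differed between Treg and Tconv of muscle at day 4, 905 higher in Treg (190 by at least 2-fold) and 2068 lower (294). The share higher in Treg was 30.4%, and 45.9% after repeated quantile normalization or 52.4% after centring, which shifted the median of all genes by 0.126 and 0.137, so the balance of directions rests on the scaling. The replicate block gave 3343 genes and the block within each day 3883. The count was 4503 without muscle Treg day 4 replicate 1, 4708 without the 4 replicate 1 arrays of day 4, 1134 with only the arrays of the comparison and 6056 with array weights. Muscle fibre markers were higher in Treg in 3 of 11, also over the list alone (adjusted p = 0.00045, and adjusted p = 0.146 with an estimated correlation). Fibroblast markers were higher in 1 of 9, also over the list alone (adjusted p = 0.00426, and adjusted p = 0.29 with an estimated correlation), in 4 without muscle Treg day 4 replicate 1, and in 2 or 3 after repeated quantile normalization or centring.

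At day 14, muscle Treg exceeded muscle Tconv in Foxp3 (40.9-fold) and the integrin chain Itgb8, which activates TGF-beta, at 10.29 ± 0.21 against 5.45 ± 0.25 (SD, n = 3 each). Klrg1 (25.7-fold), Pcsk1 (23.3-fold), Frmd5 (21.9-fold), Lrrc32 (21.2-fold), Neb (19.9-fold) and Tnfrsf9 (19.5-fold), the costimulatory receptor 4-1BB, were also higher. Il10 was higher by 3.72 ± 0.20, Havcr2 by 3.21 ± 0.18, the Treg transcription factor Ikzf2 by 3.42 ± 0.14 and Ctla4 by 2.62 ± 0.27. Pde3b (-4.98 ± 0.30), Igfbp4 (-4.22 ± 0.26), Klrk1 (-3.82 ± 0.19), the semaphorin Sema4a (-3.52 ± 0.25), the sialyltransferase St3gal6 (-3.51 ± 0.18), Ifng (-2.93 ± 0.15) and Ccr7 (-2.39 ± 0.17) were lower in Treg.

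The Treg signature was higher in 23 of 26 members and lower in 0 (24 and 0 adjusted over the list alone, median 2.17, adjusted p = 6.22e-37). Of 29 activated and tissue Treg genes 28 were higher and 1 lower, also over the list alone (adjusted p = 6.22e-37). Inhibitory receptors were higher in 7 and lower in 1 of 10 (8 and 1 adjusted over the list alone, adjusted p = 2.33e-08). Growth and repair factors were higher in 7 of 14, also over the list alone (adjusted p = 0.000398), with Penk (3.24), Pdgfb (1.37) and Tgfb1 (0.79). Lower in Treg were 11 of 12 conventional T cell-high genes (the same adjusted over the list alone, adjusted p = 1.1e-20) and 12 of 19 naive and lymphoid-homing genes (13 adjusted over the list alone, adjusted p = 1.99e-14). So were 16 of 19 Th1 and cytotoxic genes, 2 being higher (17 and 2 adjusted over the list alone, adjusted p = 1.99e-14). Gzmb, a member of the last list, was higher in Treg (2.91 ± 0.26).

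Hypoxia and glycolysis genes were higher in 9 and lower in 1 of 22 (10 and 1 adjusted over the list alone, adjusted p = 0.000616, and adjusted p = 0.305 with an estimated correlation). The oxygen sensor Egln3 (1.94) and the lactate exporter Slc16a3 (1.89) were higher and the kinase Pdk1 (-1.19) lower. Interferon-stimulated genes were lower in 12 and higher in 2 of 30 (14 and 2 adjusted over the list alone, adjusted p = 0.000616, and adjusted p = 0.305 with an estimated correlation). The lower members numbered 6 without muscle Tconv day 14 replicate 1 or 3 and 7 without muscle Treg day 14 replicate 2. Immediate-early genes were higher in 12 and lower in 4 of 30 (15 and 4 adjusted over the list alone, adjusted p = 0.00267, and adjusted p = 0.488 with an estimated correlation). Cell cycle genes did not pass (adjusted p = 0.997; 0.0222 without muscle Treg day 14 replicate 3), nor did Mki67 (0.13 ± 0.33, adjusted p = 0.884). In all, 1932 genes differed, 1124 higher in Treg (343 by at least 2-fold) and 808 lower (189), and array weights gave 3364 (1644 and 1720).

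Within muscle Treg, day 14 was set against day 4. The nuclear receptor Nr4a2, an early gene of T cell receptor signalling, rose from 8.72 ± 0.29 to 10.56 ± 0.19 (SD, n = 3 each; 3.58-fold), and Rgs2, a regulator of G protein signalling, rose 3.43-fold. Zbtb10 (2.02 ± 0.20), Ccr1 (1.81 ± 0.21), the activation marker Cd83 (1.80 ± 0.21) and Pcsk1 (1.77 ± 0.17) rose as well. Il10 rose by 1.03 ± 0.20, Klrg1 by 1.27 ± 0.25, Ikzf2 by 0.87 ± 0.14 and Ifng by 0.93 ± 0.15. The replication regulator E2f8 (-1.97 ± 0.26), the mitotic kinase Plk1 (-1.62 ± 0.35) and Mki67 (-1.58 ± 0.33) fell. Foxp3 (-0.01 ± 0.27, adjusted p = 0.983) did not pass with all arrays and stood at -0.45 without the replicate 1 arrays of day 4 (adjusted p = 0.0349, range over 18 alternatives 0.0349 to 0.987).

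Immediate-early and stress genes rose in 26 of 30 members at a median of 0.89 (28 adjusted over the list alone, adjusted p = 1.48e-14, and adjusted p = 0.307 with an estimated correlation). Without the replicate 1 arrays of day 4 the median was 0.85. Cell cycle genes fell in 52 of 60 at a median of -1.12 (55 adjusted over the list alone, adjusted p = 6.75e-27, and adjusted p = 0.387 with an estimated correlation), and 35 fell without those arrays (median -0.76). The falls numbered 24 without muscle Treg day 14 replicate 3 and 33 without muscle Treg day 4 replicate 1. Inhibitory receptors rose in 5 of 10 (8 adjusted over the list alone, adjusted p = 0.000517, and adjusted p = 0.387 with an estimated correlation), including Cd200r1 (1.59) and Pdcd1, which encodes PD-1 (1.16), and in 8 without the replicate 1 arrays of day 4. Activated and tissue Treg genes rose in 12 of 29 and fell in 0 (13 and 2 adjusted over the list alone, adjusted p = 0.00501, and adjusted p = 0.514 with an estimated correlation), Ccr8 (1.20) and Dusp4 (1.13) among them. Effector and memory genes rose in 8 of 25, also over the list alone (adjusted p = 0.0078, and adjusted p = 0.514 with an estimated correlation), led by Anxa1 (1.56), Ahnak (0.93) and the adhesion receptor Cd44 (0.88). Of these genes 5 rose after centring, 14 without the replicate 1 arrays of day 4, and 5 without muscle Treg day 14 replicate 1, 2 or 3 or day 4 replicate 2.

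Naive and lymphoid-homing genes had 6 of 19 members lower and 1 higher, also over the list alone (adjusted p = 0.0103, and adjusted p = 0.538 with an estimated correlation), with the chromatin organizer Satb1 at -1.22. Without muscle Treg day 4 replicate 3, an array with high Cd8a and Cd8b1, 1 member fell, the median went from -0.23 to -0.04 and the list did not pass (adjusted p = 0.274). It did not pass with fry either (adjusted p = 0.151), while 10 members fell without the replicate 1 arrays of day 4 or that of muscle Treg alone, and 2 without muscle Treg day 14 replicate 2 or 3. The Treg signature rose in 8 and fell in 1 of 26 (adjusted p = 0.0334, adjusted p = 0.538 with an estimated correlation and 0.261 without the replicate 1 arrays of day 4), the same counts adjusted over the list alone. It did not pass without muscle Treg day 14 replicate 3 (adjusted p = 0.0948), muscle Treg day 4 replicate 1 (0.281) or with a block within each day (0.259). Oxidative phosphorylation genes had 4 of 33 members lower, also over the list alone, at a median of -0.31 (adjusted p = 0.000684, and adjusted p = 0.538 with an estimated correlation), and the median was -0.02 without the replicate 1 arrays of day 4 (adjusted p = 0.258). It was -0.02 without muscle Treg day 4 replicate 1 alone (3 higher and 1 lower, adjusted p = 0.516), 1 member was lower without muscle Treg day 14 replicate 2, and the list did not pass with fry (adjusted p = 0.205) or the block within each day (0.0568). None of the 10 lists called in this comparison held with an estimated correlation.

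In all, 2448 genes differed, 1825 higher at day 14 (112 by at least 2-fold) and 623 lower (87). The share higher was 74.6%, and 55.3% after centring, which shifted the median of all genes by -0.105. The count was 1507 without muscle Treg day 14 replicate 2, 1558 without replicate 3, and 1574 without muscle Treg day 4 replicate 2. It was 4590 without the replicate 1 arrays of day 4, 651 with only the arrays of the comparison and 5719 with array weights. Fibroblast markers fell in 3 of 9 (5 adjusted over the list alone, median -0.32, adjusted p = 0.0053, and adjusted p = 0.514 with an estimated correlation), and in 0 without muscle Treg day 14 replicate 1, 2 or 3 or day 4 replicate 2.

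**Figure D2:**
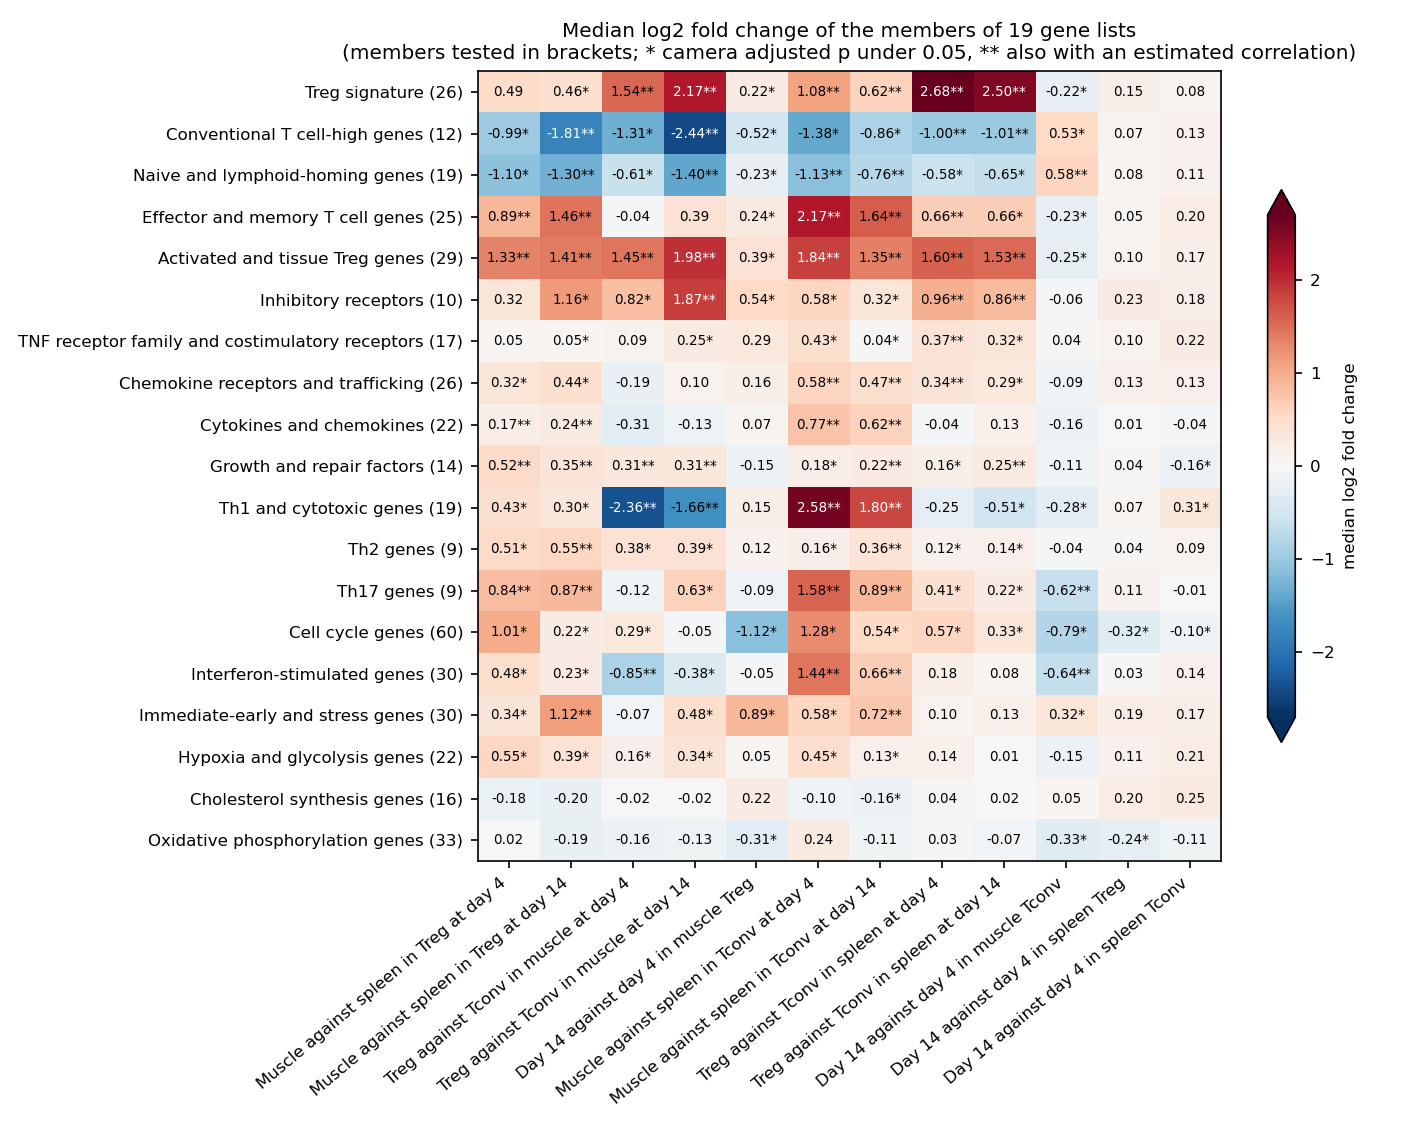
Median log2 fold change of the 19 T cell lists (vertical) in the 12 comparisons of groups (horizontal), coloured by value; 1 asterisk marks a camera adjusted p under 0.05 and a double asterisk one that holds with an estimated correlation. Activated and tissue Treg genes had a median of 1.33 in Treg and 1.84 in Tconv for muscle against spleen at day 4.

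Tconv of muscle were likewise set against Tconv of spleen. At day 4 the immunoglobulin-like receptor Lilr4b averaged 10.21 ± 0.40 in muscle and 5.15 ± 0.51 in spleen (SD, n = 3 each). Gzmb was 25.2-fold higher, the interferon-induced membrane protein Ifitm3 24.8-fold, the transcription factor Bhlhe40 18.9-fold, Ccr2 15.4-fold and Ifng 9.47-fold. Il2ra (1.88 ± 0.17), Ctla4 (2.88 ± 0.27) and Mki67 (2.17 ± 0.33) rose too. Foxp3 (-0.58 ± 0.27, adjusted p = 0.147) did not pass with all arrays and did without the replicate 1 arrays of day 4 (adjusted p = 0.0305, range over 18 alternatives 0.0305 to 0.335). Igfbp4 (-2.70 ± 0.26), Dapl1 (-2.49 ± 0.54), Atp1b1, a sodium pump subunit (-2.34 ± 0.30), Ephx1, an epoxide hydrolase (-2.19 ± 0.20), and Ccr7 (-1.71 ± 0.17) fell.

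Effector and memory genes rose in 25 of 25 members (median 2.17, adjusted p = 1.47e-31), and Th17 genes in 9 of 9 (adjusted p = 1.42e-11). Cytokines and chemokines rose in 14 of 22 (adjusted p = 5.45e-09), and all 3 lists had the same counts adjusted over the list alone. Th1 and cytotoxic genes rose in 16 and fell in 2 of 19 (17 and 2 adjusted over the list alone, adjusted p = 1.91e-20), with Klrk1 (3.79), Il18rap (3.41) and Nkg7 (3.40). Interferon-stimulated genes rose in 27 of 30 (29 adjusted over the list alone, median 1.44, adjusted p = 1.63e-29), and activated and tissue Treg genes in 24 of 29 (25 adjusted over the list alone, adjusted p = 2.63e-25). Naive and lymphoid-homing genes fell in 15 of 19 (17 adjusted over the list alone, adjusted p = 1.48e-18). Cell cycle genes rose in 57 of 60 (59 adjusted over the list alone, median 1.28, adjusted p = 1.48e-18, and adjusted p = 0.161 with an estimated correlation), and 49 did without the replicate 1 arrays of day 4. In all, 2149 genes differed, 1688 higher in muscle (516 by at least 2-fold) and 461 lower (75). The share higher was 78.5%, and 56% after repeated quantile normalization or 50.6% after centring, with shifts of the median of all genes of -0.133 and -0.156. Erythroid and platelet markers had a median of -0.23 (adjusted p = 0.0398, and adjusted p = 0.303 with an estimated correlation) and did not pass without muscle Tconv day 4 replicate 1 (adjusted p = 0.0904) or spleen Tconv day 4 replicate 1 (0.128) or 3 (0.0552).

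At day 14, muscle Tconv exceeded spleen Tconv in Lilr4b (4.35 ± 0.26), its relative Lilrb4a (3.78 ± 0.25), the cytokine signalling inhibitor Socs2 (3.49 ± 0.17) and Anxa1 (3.45 ± 0.28). Slc16a5 (-1.83 ± 0.26) and Cxcr5 (-1.59 ± 0.21) fell. Ifng rose by 2.92 ± 0.15 and Ccr2 by 3.15 ± 0.19. Effector and memory genes rose in 25 of 25, also over the list alone (adjusted p = 2.63e-47). Th1 and cytotoxic genes rose in 15 and fell in 2 of 19 (16 and 2 adjusted over the list alone, adjusted p = 2.87e-26) and interferon-stimulated genes in 22 of 30 (23 adjusted over the list alone, adjusted p = 4.9e-24). Immediate-early genes rose in 20 of 30 (24 higher and 1 lower adjusted over the list alone, adjusted p = 2.74e-20), and in 13 without spleen Tconv day 14 replicate 2. Cell cycle genes rose in 6 of 60 (11 adjusted over the list alone, adjusted p = 1.03e-10, and adjusted p = 0.322 with an estimated correlation and 0.0806 with fry). Of these genes 11 rose after centring, 18 without the replicate 1 arrays of day 4, and 3 without muscle Tconv day 14 replicate 1 or spleen Tconv day 14 replicate 2. In all, 1005 genes differed, 679 higher in muscle (233 by at least 2-fold) and 326 lower (25). The count was 1610 without the replicate 1 arrays of day 4, 1749 with only the arrays of the comparison and 2274 with array weights.

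In the spleen at day 4, Treg exceeded Tconv in Il2ra, at 11.03 ± 0.18 against 5.69 ± 0.19 (SD, n = 3 each), Lrrc32 (27-fold), Foxp3 (20.4-fold) and Klrg1 (15.8-fold). Pde3b (-4.77 ± 0.30), Dapl1 (-3.57 ± 0.54), the lipid flippase Atp8b4 (-3.21 ± 0.31) and Mctp2 (-3.11 ± 0.30) were lower in Treg. The Treg signature was higher in 26 of 26 members, also over the list alone (median 2.68, adjusted p = 4.69e-70), and 26 of 29 activated and tissue Treg genes were higher (26 higher and 1 lower adjusted over the list alone, adjusted p = 1.08e-41). Of 1138 genes called, 808 were higher in Treg (227 by at least 2-fold) and 330 lower (66), 71% higher against 60.3% after repeated quantile normalization. The replicate block gave 1257, the block within each day 1481 and the arrays of the comparison alone 693.

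At day 14 in the spleen, Lrrc32 (5.15 ± 0.22), Foxp3 (4.98 ± 0.27), Il2ra (4.91 ± 0.17) and Klrg1 (4.38 ± 0.25) were again higher in Treg, and Pde3b (-5.09 ± 0.30) and Dapl1 (-3.62 ± 0.54) lower. All 26 of 26 Treg signature genes were higher, also over the list alone (adjusted p = 7.17e-68). Growth and repair factors were higher in 4 of 14 (5 adjusted over the list alone, adjusted p = 6.64e-06), with Penk at 3.35. Th1 and cytotoxic genes were lower in 9 and higher in 2 of 19 (11 and 2 adjusted over the list alone, adjusted p = 7.2e-05, and adjusted p = 0.0523 with an estimated correlation), with the natural killer receptor Klrd1 at -2.64. Muscle fibre markers were higher in 3 of 11, also over the list alone (adjusted p = 0.00429, and adjusted p = 0.184 with an estimated correlation). Of 1226 genes called, 751 were higher in Treg (222 by at least 2-fold) and 475 lower (84). The replicate block gave 1373, the block within each day 1580, leaving out the replicate 1 arrays of day 4 1852 and array weights 2516.

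In muscle Tconv, day 14 differed from day 4 in 95 genes. Gzmb fell from 10.11 ± 0.66 to 8.30 ± 0.16 (SD, n = 3 each), a change of -1.81 ± 0.26, and Ifitm3 (-1.38 ± 0.24) and the interferon-induced exonuclease Isg20 (-1.15) fell. Igfbp4 (1.54 ± 0.26), Ccr7 (1.23 ± 0.17) and the sialyltransferase St8sia6 (1.19 ± 0.12) rose, while Foxp3 (0.24 ± 0.27) and Ifng (0.23 ± 0.15) did not pass. Interferon-stimulated genes fell in 12 of 30 members (26 adjusted over the list alone, median -0.64, adjusted p = 1.74e-32), and in 19 without the replicate 1 arrays of day 4. Th17 genes fell in 5 of 9 (8 adjusted over the list alone, adjusted p = 9.16e-12), and naive and lymphoid-homing genes rose in 7 of 19 (11 adjusted over the list alone, adjusted p = 2.3e-16). Without muscle Tconv day 14 replicate 1 or 2 or day 4 replicate 1, 2 or 3, the interferon-stimulated genes that fell numbered 6, 4, 6, 5 and 4, and the naive genes that rose 3, 3, 3, 4 and 4. Th17 falls numbered 2 without muscle Tconv day 14 replicate 2 or day 4 replicate 3. No cell cycle gene passed in limma over all genes, 51 of 60 fell when adjusted over the list alone, and the list had a median of -0.79 (adjusted p = 1.4e-30, and adjusted p = 0.132 with an estimated correlation). Without the replicate 1 arrays of day 4, 8 fell and the median was -0.78, and 4 fell after centring. Of the 95 genes, 51 were higher at day 14 (9 by at least 2-fold) and 44 lower (10), a balance that turned with the setting. After repeated quantile normalization 90 were higher and 43 lower, after centring 82 and 82, with a pseudocount of 16 50 and 52, and with the block within each day 34 and 49. The count fell to 40 or 31 without muscle Tconv day 14 replicate 1 or 2 and to 52, 59 or 36 without muscle Tconv day 4 replicate 1, 2 or 3. It was 190 with the replicate block (75 higher and 115 lower), 290 without the replicate 1 arrays of day 4 (84 and 206), 193 with only the arrays of the comparison (63 and 130), 164 after centring, 63 without a filter (33 and 30) and 738 with array weights (285 and 453). Macrophage and monocyte markers had 1 of 7 members lower, also over the list alone (adjusted p = 0.014, and adjusted p = 0.132 with an estimated correlation).

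In spleen Treg no gene differed between days 14 and 4 in limma at an adjusted p under 0.05 (619 at an unadjusted p under 0.05). Foxp3 (0.16 ± 0.27), Il10 (0.37 ± 0.20), Klrg1 (0.46 ± 0.25) and Gzmb (0.09 ± 0.26) did not pass. In spleen Tconv limma called 0 genes as well (2022 at an unadjusted p under 0.05), with Foxp3 at -0.47 ± 0.27. Cell cycle genes had a median of -0.32 in spleen Treg (adjusted p = 1.4e-16, and adjusted p = 0.897 with an estimated correlation) with 0 members called over all genes or over the list alone, and it did not pass with the block within each day (adjusted p = 0.555) or fry (0.729). Oxidative phosphorylation genes had a median of -0.24 in spleen Treg (adjusted p = 1.81e-05, and adjusted p = 0.897 with an estimated correlation), and -0.05 without spleen Treg day 4 replicate 1 (adjusted p = 0.43). In spleen Tconv camera called 1 list up and 4 down, with 0 members called over all genes. Th1 and cytotoxic genes had a median of 0.31 (5 higher adjusted over the list alone, adjusted p = 0.00851, and adjusted p = 0.321 with an estimated correlation), and did not pass without spleen Tconv day 4 replicate 2 (adjusted p = 0.0662; 3 members rose) or 3 (0.0512). Cell cycle genes had a median of -0.10 (adjusted p = 0.00851, and adjusted p = 0.812 with an estimated correlation) and did not pass without spleen Tconv day 14 replicate 2 (adjusted p = 0.0574) or 3 (0.276) or day 4 replicate 2 (0.118). Growth and repair factors had a median of -0.16 (1 lower adjusted over the list alone, adjusted p = 0.0239, and adjusted p = 0.321 with an estimated correlation) and did not pass without day 14 replicate 1 (adjusted p = 0.0551) or day 4 replicate 3 (0.0847). Erythroid and platelet markers had a median of -0.24 (adjusted p = 0.0146, and adjusted p = 0.486 with an estimated correlation), lost without replicate 1 of day 14 (0.0578) or day 4 (0.0517), and muscle fibre markers one of -0.18 (adjusted p = 0.00124, and adjusted p = 0.321 with an estimated correlation). The count in spleen Tconv was 390 without spleen Tconv day 4 replicate 2, and 569 genes were called in spleen Treg with array weights.

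Whether the change from spleen to muscle differed between Treg and Tconv was tested by interaction. At day 4 Pcsk1 rose in Treg (8.90 against 5.46) but averaged 5.66 ± 0.17 in muscle and 5.74 ± 0.18 in spleen Tconv (SD, n = 3 each), an interaction of 3.53 ± 0.24. Havcr2 (2.18 ± 0.25), Ccr3 (2.79 ± 0.36), the lysosomal protease Lgmn (2.83 ± 0.37) and Il10 (1.46 ± 0.28) had interactions toward Treg. Those of Klrk1 (-3.60 ± 0.26), the semaphorin receptor Nrp1 (-3.42 ± 0.17), Ifng (-3.38 ± 0.21) and the inflammatory protease Casp1 (-3.20 ± 0.41) went toward Tconv, as did Ctla4 (-1.95 ± 0.38) and Il2ra (-1.24 ± 0.24). The tissue change of Klrg1 (0.00 ± 0.35, adjusted p = 0.998) did not differ beyond the spread. That of Gzmb (-0.78 ± 0.36, adjusted p = 0.17) passed without muscle Tconv day 4 replicate 1 (adjusted p = 0.0307, range over 24 alternatives 0.0307 to 0.43).

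By list, the change was lower in Treg for 15 of 19 Th1 and cytotoxic genes and higher for 1 (16 and 1 adjusted over the list alone, median -1.76, adjusted p = 5.78e-16). It was also lower for 22 of 30 interferon-stimulated genes (25 adjusted over the list alone, median -1.26, adjusted p = 2.69e-16) and 13 of 25 effector and memory genes (16 adjusted over the list alone, median -1.04, adjusted p = 9.71e-12). The same held for 14 of 26 Treg signature genes, with 1 higher (15 and 2 adjusted over the list alone, median -1.07, adjusted p = 2.53e-08) and 9 of 22 cytokines and chemokines, with 2 higher (12 and 2 adjusted over the list alone, median -0.59, adjusted p = 0.00563). The interaction covered 1174 genes, 261 higher in Treg (77 by at least 2-fold) and 913 lower (368), and the 22.2% higher became 40.8% or 46.6% under quantile normalization or centring, with shifts of 0.16 and 0.182. It covered 2512 without muscle Treg day 4 replicate 1, 1871 with the block within each day and 477 with only the arrays of the comparison. Higher in Treg were 1 of 11 muscle fibre markers (adjusted p = 0.0034, and adjusted p = 0.24 with an estimated correlation) and 1 of 9 fibroblast markers (adjusted p = 0.0034, and adjusted p = 0.246 with an estimated correlation), the same counts over each list alone. Erythroid and platelet markers had a median of 0.38 (adjusted p = 0.0242, and adjusted p = 0.337 with an estimated correlation) and did not pass without spleen Tconv (adjusted p = 0.0741) or spleen Treg day 4 replicate 1 (0.0534).

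At day 14 the interaction was 5.01 ± 0.24 for Pcsk1, 3.85 ± 0.29 for Ccr1, 3.61 ± 0.20 for Frmd5, 3.04 ± 0.19 for Pcyt1a, 2.72 ± 0.25 for Havcr2 and 2.00 ± 0.28 for Il10. On the other side stood the potassium channel gene Kcnk5 (-3.18 ± 0.21), Klrk1 (-3.16 ± 0.26), Socs2 (-3.03 ± 0.24), Gpr83 (-3.00 ± 0.27), Ifng (-2.06 ± 0.21) and Ccr7 (-1.44 ± 0.24). The list that held with an estimated correlation was Th1 and cytotoxic genes, with 9 of 19 lower and 1 higher (11 and 1 adjusted over the list alone, median -1.01, adjusted p = 3.09e-15). Naive and lymphoid-homing genes were lower in 9 and higher in 2 of 19 (11 and 3 adjusted over the list alone, adjusted p = 5.12e-09, and adjusted p = 0.0996 with an estimated correlation). Of 423 genes, 209 were higher in Treg (98 by at least 2-fold) and 214 lower (123). The count was 713 without the replicate 1 arrays of day 4, 737 with only the arrays of the comparison and 1097 with array weights.

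**Figure D3:**
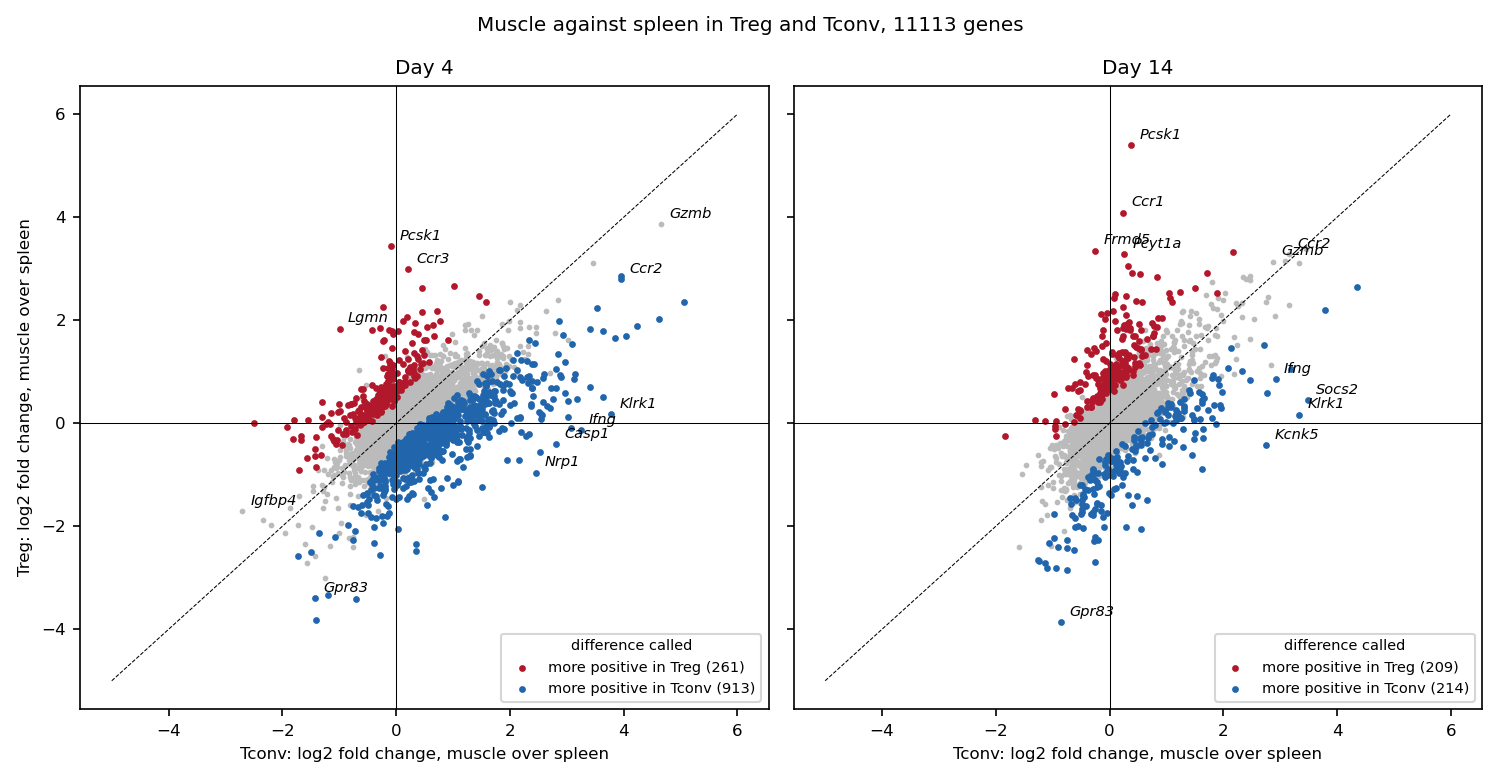
Log2 fold change of muscle against spleen in Tconv (horizontal) and Treg (vertical) for each gene at days 4 and 14, with genes called in the interaction coloured. At day 4, 261 coloured genes lie toward Treg and 913 toward Tconv, and at day 14, 209 and 214.

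Whether muscle Treg and Tconv changed differently from day 4 to day 14 was tested in the same way. The change was greater in Treg for Rasgef1b (2.13 ± 0.26), Cysltr2, a leukotriene receptor (1.96 ± 0.23), and Cd83 (1.78 ± 0.29), and greater in Tconv for Igfbp4 (-2.28 ± 0.36), Ccr7 (-1.78 ± 0.24) and Rflnb (-1.75 ± 0.23). Immediate-early genes were higher in 6 of 30 (14 adjusted over the list alone, median 0.73, adjusted p = 5.51e-09, and adjusted p = 0.114 with an estimated correlation), and 20 were without the replicate 1 arrays of day 4. They numbered 11 without muscle Treg day 4 replicate 1, 3 without muscle Treg day 14 replicate 3 and 2 without muscle Tconv day 14 replicate 2. None of the 15 lists called held with an estimated correlation. Of 284 genes, 236 were higher in Treg (78 by at least 2-fold) and 48 lower (22), with 83.1% higher against 69.7% and 66% under quantile normalization and centring (shifts of -0.107 and -0.128). The count was 997 or 173 without muscle Treg day 4 replicate 1 or 2, 159, 169 or 159 without muscle Treg day 14 replicate 1, 2 or 3, 186 or 120 without muscle Tconv day 4 replicate 2 or 3, and 117 without muscle Tconv day 14 replicate 2. It was 1649 without the replicate 1 arrays of day 4, 578 with the block within each day, 137 with only the arrays of the comparison and 2496 with array weights. Fibroblast markers had a median of -0.22 (adjusted p = 0.0125, and adjusted p = 0.321 with an estimated correlation) and did not pass without muscle Tconv day 14 replicate 2 (adjusted p = 0.0562) or muscle Treg day 4 replicate 2 (0.095). Muscle fibre markers had one of -0.21 (adjusted p = 0.0318, and adjusted p = 0.353 with an estimated correlation), lost without those arrays (0.0937 and 0.214), muscle Tconv day 4 replicate 1 (0.0657) or muscle Treg day 14 replicate 1 (0.156).

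Between tissues, the change of Treg from day 4 to day 14 was greater in muscle for Ccr1 (2.02 ± 0.29) and Pcsk1 (1.95 ± 0.24), and the interferon-induced GTPase Gbp2b (-1.30 ± 0.18) and Rflnb (-1.30 ± 0.23) changed the other way. Immediate-early genes were higher in 5 of 30 (15 adjusted over the list alone, median 0.72, adjusted p = 4.11e-18, and adjusted p = 0.145 with an estimated correlation). After repeated quantile normalization 9 were higher, and without the replicate 1 arrays of day 4 20 were at a median of 0.81. Without muscle Treg day 14 replicate 2 or 3, or spleen Treg day 14 replicate 1 or 3, they numbered 2, 1, 2 and 1. Without replicate 1 of day 4 they numbered 8 (muscle Treg) or 9 (spleen Treg), and 2 without spleen Treg day 4 replicate 2. Of 92 genes, 72 were higher (32 by at least 2-fold) and 20 lower (10), 78.3% higher against 68.1% after centring. The count was 214 without muscle Treg day 4 replicate 1, 59, 38 or 44 without muscle Treg day 14 replicate 1, 2 or 3, 46 or 33 without spleen Treg day 14 replicate 1 or 3 and 42 or 47 without spleen Treg day 4 replicate 2 or 3. It was 355 without the replicate 1 arrays of day 4, 270 with the block within each day, 152 with the replicate block, 160 after repeated quantile normalization, 17 with only the arrays of the comparison and 1286 with array weights. Fibroblast markers had a median of -0.34 (adjusted p = 0.00385, and adjusted p = 0.367 with an estimated correlation), with an adjusted p of 0.0514 without muscle Treg day 4 replicate 2.

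The muscle responses overlapped beyond the number expected from the counts alone. In Treg, 647 genes were higher in muscle at both days (107 expected) and 448 lower (72.6), with 5 in opposite directions, and the fold changes correlated across genes at a Pearson r of 0.746 and a Spearman rho of 0.583. Between Treg and Tconv, 698 genes were higher in muscle in both at day 4 (182 expected), 225 lower (53.3) and 77 opposite, and at day 14 the numbers were 431 (60.3), 184 (18.4) and 17. The Treg against Tconv difference was shared between muscle and spleen in 353 higher (65.8) and 200 lower genes (61.4) at day 4, with 89 opposite, and in 515 (76) and 296 (34.5) at day 14, with 16 opposite. Genes are not independent, so no p is attached to these counts.

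Markers of other cells lay near or below the filter level of 6.46. The median log2 intensity of their 10 lists over the 8 groups ran from 4.22 in NK and CD8 T cell genes to 6.48 in muscle fibre genes. Single members stood above their list. Neb averaged 10.25 in muscle Treg and 5.93 in muscle Tconv at day 14. At that day Cd74, the invariant chain of antigen presentation, was higher in Treg by 3.57 ± 0.26, Mmp9, a matrix protease of many leukocytes, by 1.22 ± 0.21 and Timp2, an inhibitor of such proteases, by 1.48 ± 0.13. Pecam1 was lower in muscle than in spleen Treg (-1.15 ± 0.14) and Ctss, a lysosomal protease, lay at 10.28 to 10.92 in all groups.

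**Figure D4:**
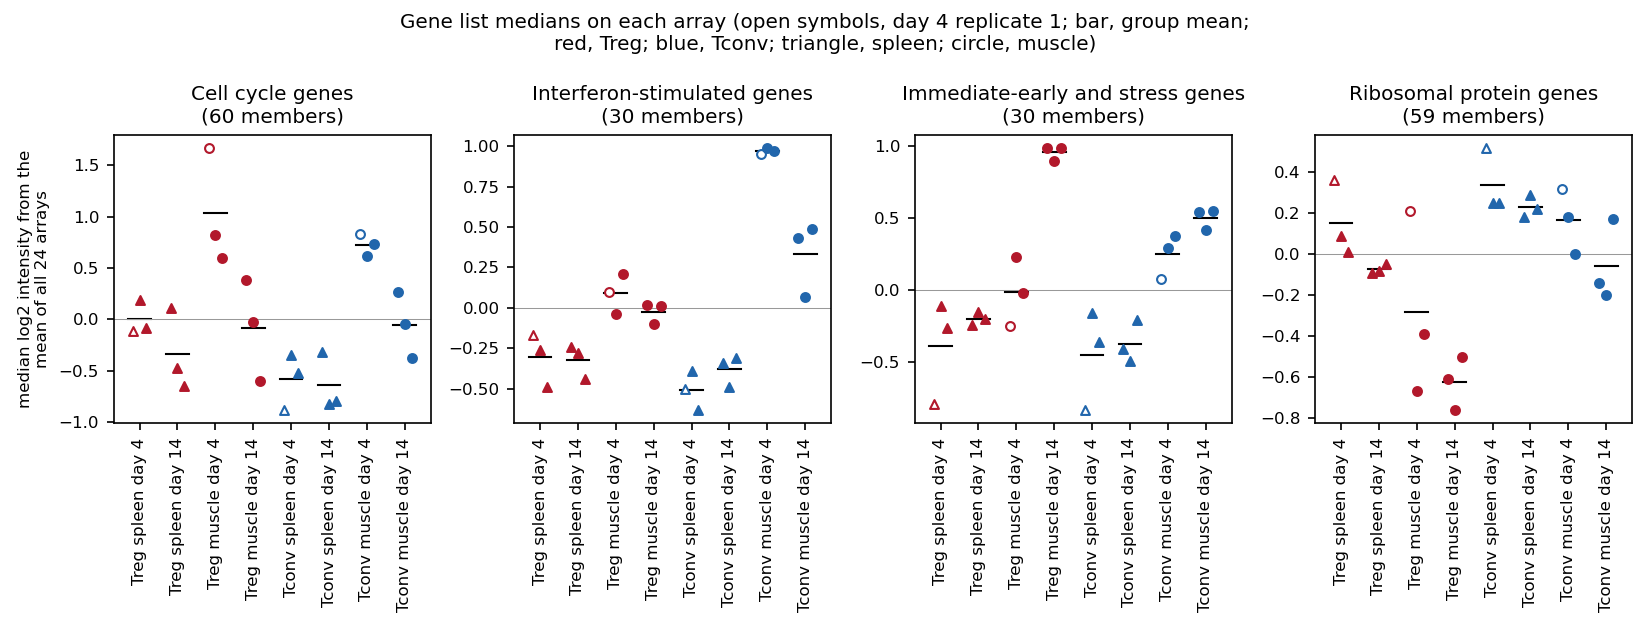
Median log2 intensity of 60 cell cycle, 30 interferon-stimulated, 30 immediate-early and 59 ribosomal protein genes in each array, relative to the mean of all 24 arrays, with open symbols for the replicate 1 arrays of day 4. The ribosomal protein genes of those 4 arrays lie higher than in the other arrays of their group by 0.22 to 0.78.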

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

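The tests of a shared step, of CD8 T cells, of conventional T cells and of a wrong label in 1 array, and of muscle handling were chosen after their results were seen, as were camera on the interactions and with arrays left out, the block within each day and leaving out the replicate 1 arrays of day 4 together.

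What drew attention were effects that differed between cell types, tissues or days by an interaction test in limma. At day 4 the change from spleen to muscle differed between Treg and Tconv in 1174 genes, with higher values in Treg for Pcsk1 (3.53), Lgmn (2.83), Ccr3 (2.79), Dapl1 (2.50), Havcr2 (2.18), Il10 (1.46) and Foxp3 (1.25). Lower values stood at -3.60 for Klrk1, -3.42 for Nrp1, -3.38 for Ifng, -3.20 for Casp1, -1.95 for Ctla4, -1.24 for Il2ra, -1.14 for Ccr2 and -1.05 for Ikzf2. Medians of lists were -1.76 for Th1 and cytotoxic genes, -1.26 for interferon-stimulated genes, -1.07 for the Treg signature, -1.04 for effector and memory genes and -0.59 for cytokines and chemokines. With only the arrays of the comparison Dapl1 (adjusted p = 0.191), Foxp3 (0.167) and Ccr2 (0.0501) did not pass. These are the highest of 24 alternatives, and the lowest were 4.77e-05, 0.000317 and 0.00133. Dapl1 did not pass without muscle Tconv day 4 replicate 2 (adjusted p = 0.0667) or 3 (0.0959), spleen Tconv day 4 replicate 1 (0.0851) or 3 (0.0667), or spleen Treg day 4 replicate 2 (0.0818) or 3 (0.0677). Without muscle Treg day 4 replicate 3, an array with high Cd8a, its interaction was 1.31 (adjusted p = 0.0044). Foxp3 did not pass without muscle Tconv day 4 replicate 2 (adjusted p = 0.0767) or 3 (0.0827), spleen Tconv day 4 replicate 1 (0.0913) or 3 (0.0882), muscle Treg day 4 replicate 2 (0.126) or 3 (0.0928), or spleen Treg day 4 replicate 1 (0.108). Without muscle Treg day 4 replicate 1 the count was 2512.

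At day 14 the same interaction held 423 genes. Values were 5.01 for Pcsk1, 3.85 for Ccr1, 3.61 for Frmd5, 3.04 for Pcyt1a, 2.72 for Havcr2 and 2.00 for Il10, and -3.18 for Kcnk5, -3.16 for Klrk1, -3.03 for Socs2, -3.00 for Gpr83, -2.06 for Ifng and -1.44 for Ccr7. Th1 and cytotoxic genes had a median of -1.01.

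The change from day 4 to day 14 in muscle differed between Treg and Tconv in 284 genes, among them Rasgef1b (2.13), Cd200r4 (2.00), Cysltr2 (1.96), Cd83 (1.78) and Ikzf2 (0.84), and Igfbp4 (-2.28), Atp1b1 (-1.95), Ccr7 (-1.78) and Rflnb (-1.75). Over 24 alternatives the adjusted p of Ikzf2 ran from 0.00228 to 0.0865. It did not pass without muscle Tconv day 14 replicate 2 (adjusted p = 0.0865), muscle Tconv day 4 replicate 3 (0.0679), muscle Treg day 14 replicate 3 (0.0743) or muscle Treg day 4 replicate 2 (0.0538). Single arrays that moved the count by over 1.5 times gave 997 and 173 without muscle Treg day 4 replicates 1 and 2, 159, 169 and 159 without muscle Treg day 14 replicates 1, 2 and 3, 186 and 120 without muscle Tconv day 4 replicates 2 and 3, and 117 without muscle Tconv day 14 replicate 2.

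The day change of Treg differed between muscle and spleen in 92 genes, among them Ccr1 (2.02), Pcsk1 (1.95), Cd200r4 (1.78), Anxa1 (1.74) and Ifng (1.00), and Rflnb (-1.30), Gbp2b (-1.30), Satb1 (-1.28) and Ust (-1.12). Over 24 alternatives the adjusted p ran from 9.59e-05 to 0.152 for Anxa1, 4.29e-06 to 0.157 for Satb1, 2.9e-05 to 0.119 for Ust and 0.000466 to 0.0824 for Ifng. Anxa1 did not pass when an array other than muscle Treg day 14 replicate 3, muscle Treg day 4 replicate 1 or spleen Treg day 14 replicate 2 was left out (adjusted p up to 0.106). Ifng did not pass without muscle Treg day 14 replicate 2 or 3, spleen Treg day 14 replicate 1 or 3 or spleen Treg day 4 replicate 2 or 3 (up to 0.0824). Satb1 did not without muscle Treg day 14 replicate 1 or day 4 replicate 2, spleen Treg day 14 replicate 1 or 3 or spleen Treg day 4 replicate 1 (up to 0.0721). Ust did not pass without spleen Treg replicate 3 of day 14 (0.0651) or day 4 (0.0506). Single arrays that moved the count by over 1.5 times gave 214 without muscle Treg day 4 replicate 1, 59, 38 and 44 without muscle Treg day 14 replicates 1, 2 and 3, 46 and 33 without spleen Treg day 14 replicates 1 and 3, and 42 and 47 without spleen Treg day 4 replicates 2 and 3.

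Of the 100 splits of the 12 arrays per interaction, 6 gave as many genes as the real groups at day 4 (highest other 1636), 9 at day 14 (1007), 8 for cell type by day (989) and 11 for tissue by day (2105). The splits thus do not exclude chance for these counts. Of the other splits that gave as many, 5 of 5, 8 of 8, 7 of 7 and 7 of 10 left 1 side of the contrast as in the real groups, so that a main effect entered. Among splits that mixed both sides, 0, 0, 0 and 3 gave as many, with highest counts of 1158, 24, 10 and 2060. The splits with 1158 and 2060 (real 1174 and 92) set their day 4 replicate 1 arrays on the same side. This points to a sample structure, and the block within each day gave 1871 and 270.

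For the 12 comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. In the comparisons of muscle with spleen, the real and highest other counts were 2485 and 1423 in Treg at day 4, 1615 and 0 at day 14, 2149 and 0 in Tconv at day 4 and 1005 and 0 at day 14. For Treg against Tconv they were 2973 and 406 in muscle at day 4, 1932 and 0 at day 14, 1138 and 1 in spleen at day 4 and 1226 and 0 at day 14. For day 14 against day 4 they were 2448 and 2 in muscle Treg, 95 and 0 in muscle Tconv and 0 and 0 in both spleen populations, where all 10 of 10 splits equal the real one, against 1 of 10 elsewhere. The split with 1423 put both replicate 1 arrays of day 4 together and parted 1 pair, as did that with 406, while splits parting 3 pairs, as the real one does, gave 0. The blocked counts within each day were 3190 and 3883.

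Replicates 1 of day 14 and 3 of day 4 departed alike across groups (r 0.346 to 0.414 and 0.318 to 0.489). So did the replicate 1 arrays of day 4 (0.342 to 0.772), which may align replicate 3. Genes highest in them were Rnf7 (3.88), Cox6a1 (3.53), Mrpl42 (3.37) and Sec61b (3.31), and lowest Rmrp (-1.38) and Tmem38b (-1.2), while 51 small nucleolar RNA genes, chosen after the data were seen, had a median of -0.28. Marker lists of other cells rose by a median of at most 0.08 but hold 1 to 11 tested genes, so those cells stay open. Against unequal array distributions stands the ribosomal shift of 0.34 after quantile normalization. A shared step of sorting, amplification, hybridization or processing stays open, as labels name no batch. A biological difference between the mice behind these pools was not tested.

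In muscle Treg day 4 replicate 3, Cd8a lay 3.46 above the higher of the other 2 arrays of its group and Cd8b1 2.27, with Klrd1 (2.02), Ctsw (1.17), Dapl1 (3.21) and Ccr9 (1.44) also higher, and Cd8b1 averaged 9.17 in the group. Against conventional CD4 T cells as the source of Cd8a and Cd8b1 stands their excess of at least 2.22 over the highest of the 12 Tconv arrays, and against a wrong label a Foxp3 value of 12.53. Some conventional T cells beside them stay open, as Pde3b lay 1.37 higher, Cd40lg at -0.03 and 12 conventional T cell-high genes at a median of 0.42. CD8 T cells in that pool may account for the smallest excess of 2.27, although the sort excluded CD8a. CD8 transcripts in Treg themselves were not tested.

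Immediate-early genes rose from day 4 to day 14 in muscle Treg by a median of 0.89. Against handling acting alike on all muscle T cells stands the median of 0.32 in muscle Tconv. The interaction had an adjusted p = 5.51e-09, and 0.114 with an estimated correlation. Against the day 4 replicate 1 arrays stands the median of 0.85 without them. Handling that acts more on Treg, the stage of repair and the mice of each day stay open, as does handling for muscle against spleen.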

How the results depend on the processing

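The block within each day, camera on interactions and with arrays left out, and leaving out the day 4 replicate 1 arrays together were chosen after results were seen. Alternatives gave 16015 values for 862 gene results, many named for large folds. Of them, 15285 kept their side of the threshold, 625 no longer passed, 105 newly passed and 0 passed the other way. Fitting only the arrays of the comparison ended most calls, single arrays aside (83 of 862). With its own spread and fewer degrees of freedom, counts fell at day 4 but rose at day 14. Their order reversed in muscle against spleen Treg (870 and 2167) and muscle Treg against Tconv (1134 and 2688). Other counts stayed within 1.5 times of the main count where none is given, and causes were untested unless stated. Values near the background limit what arrays resolve, as RMA compresses them.

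Unconverged array weights ran from 0.07 to 5.08, the last on the array with high Cd8a (others of its group 0.18 and 0.34). Their counts were 4883 and 3614 for muscle against spleen in Treg at days 4 and 14 and 2274 in Tconv at day 14. Treg against Tconv gave 6056 and 3364 in muscle at both days and 2516 in spleen at day 14. By day, muscle Treg and Tconv and spleen Treg gave 5719, 738 and 569. Tissue by cell type at day 14 had 1097, cell type by day 2496 and tissue by day 1286. Shared genes numbered 2302 between days in Treg and 1410 between cell types at day 14.

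With only the arrays of the comparison they were 870 for muscle against spleen in Treg at day 4, 1749 in Tconv at day 14, 1134 and 693 for Treg against Tconv at day 4 in muscle and spleen, and 651 and 193 for day 14 against day 4 in muscle Treg and Tconv. They were 477 and 737 for tissue by cell type at days 4 and 14, 137 for cell type by day, 17 for tissue by day, and 661 and 409 for genes shared between days in Treg and between cell types at day 4. Without the replicate 1 arrays of day 4 they were 2434 and 1610 for muscle against spleen at day 14 in Treg and Tconv, 4708 for Treg against Tconv in muscle at day 4 and 1852 in spleen at day 14. They were 4590, 290 and 2 for day 14 against day 4 in muscle Treg, muscle Tconv and spleen Tconv, 713, 1649 and 355 for tissue by cell type at day 14, cell type by day and tissue by day, and 934 shared genes at day 14.

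The replicate block gave 190 for muscle Tconv by day and 152 for tissue by day, and the block within each day 4 for spleen Tconv by day, 1871 for tissue by cell type at day 4, 578 for cell type by day and 270 for tissue by day. Day changes of muscle Tconv numbered 63 without a filter and 164 after centring, that of spleen Tconv 1 and tissue by day 160 after repeated quantile normalization. Of 148 list calls in the 12 comparisons of groups, 62 held with an estimated correlation. Fry kept 126 of the 148 and made 143 in all, the replicate block 152, the block within each day 156 and leaving out the replicate 1 arrays of day 4 155.

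Leaving out 1 array at a time, which also shrinks a group to 2, gave 1819 to 3394 and 1252 to 1443 for muscle against spleen in Treg at days 4 and 14 and 1520 to 2552 and 712 to 815 in Tconv. It gave 1985 to 4503 and 1550 to 1666 for Treg against Tconv in muscle, and 908 to 1128 and 893 to 1001 in spleen. The ranges were 1507 to 3453, 31 to 75, 0 to 0 and 0 to 390 for the days in muscle Treg, muscle Tconv, spleen Treg and spleen Tconv. They were 787 to 2512 and 343 to 378 for tissue by cell type, 117 to 997 for cell type by day, 33 to 214 for tissue by day, 906 to 1200, 750 to 932 and 465 to 567 for the shared genes, and 146 to 152 list calls. Of single list results by array left out, 2608 kept their side of the threshold, 69 no longer passed and 82 newly passed. Another 1 newly passed in the other direction, oxidative phosphorylation genes in cell type by day without muscle Treg day 4 replicate 1 (adjusted p = 0.0297).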

Other observations

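The values of this part from probe sets without a single gene were obtained with tests chosen after the results were seen, and the gene lists were fixed before.

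Chemokine receptors and trafficking genes rose in 17 and fell in 3 of 26 members in muscle against spleen Tconv at day 4, also over the list alone (adjusted p = 5.54e-07), with Cxcr6 (3.63 ± 0.34) and the integrin chain Itga1 (2.75 ± 0.17) among the rises. At day 14, 12 rose and 3 fell, or 1 after repeated quantile normalization (16 and 4 adjusted over the list alone, adjusted p = 8.48e-10), with Cxcr6 at 2.76 ± 0.34 and Itga1 at 2.77 ± 0.17 (SE, 3 arrays each).

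Hypoxia and glycolysis genes rose in 10 and fell in 1 of 22 in muscle against spleen Treg at day 4 (14 and 2 adjusted over the list alone, adjusted p = 1.58e-05, and adjusted p = 0.183 with an estimated correlation). Egln3 rose by 2.46 ± 0.14 and the glycolytic enzyme Tpi1 by 1.31 ± 0.20, while Pdk1, which holds pyruvate back from mitochondria, stood at -1.19 ± 0.13.

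Among 1853 probe sets with several genes or none that passed the filter, tested apart, limma called 367 for muscle against spleen in Treg at day 4, 170 at day 14, 408 for Treg against Tconv in muscle at day 4, 280 at day 14 and 295 between days in muscle Treg.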
